A study of Arabidopsis thaliana with 40 samples.

How the data were processed

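Messenger RNA of Arabidopsis thaliana shoots was measured in 40 libraries, 8 in each of 5 groups, made with Lasy-Seq from 200 ng of total RNA. Per the labels, plants grew in pots of clay granule soil at 22 °C with 16 h of light at 110 to 140 µmol per square metre and second and 8 h of darkness. Samples were grouped by their titles. Gene counts were made and deposited by the authors as whole numbers of reads per gene, with no normalization. Per the submitters' processing notes, the tools named are bcl2fastq, Trimmomatic, HISAT2, featureCounts and DESeq2, and the genome build is TAIR10; versions and settings are not given in the sources used here. A further table deposited by the authors holds a normalized signal, which was checked to be the counts divided by median-ratio size factors and was used for that check only. Whether counting used strand or reads that map to several places is not given in the sources used here, so values of near-identical copies (BIP1 and BIP2, the LHCB1 and RBCS genes, COR15A and COR15B, CBF1 to CBF3, the glutaredoxins beside AT4G15690) and of overlapping genes are uncertain.

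Gene symbols, products, transcript lengths and GC content came from the RefSeq annotation of TAIR10.1, which matched 26719 of 27416 identifiers; no coordinates were taken from it. No library had under 200000 counts, so none was left out, and 2296 genes had no count in any library. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 3.65 to 25), and each was counted as 1 sample. This argues against repeated counts of the same library and does not show that replicates were separate plants. The depth of 2098593 to 9211896 counts puts the floor of 3 counts at 1.43 to 0.326 CPM.

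The tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes passing filterByExpr over the 5 groups (16579), TMM scaling, a mean per group for all 40 libraries in 1 model, and the quasi-likelihood F test with Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. All 6 comparisons came from that model: 6 days on water against the start, ethanol against water before and after freezing, freezing after water and after ethanol, and the difference of both freezing effects. The SE is the absolute log2 fold change divided by the square root of F. CPM are counts divided by the library total scaled by TMM, as edgeR's cpm function gives them.

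The 28 gene lists held 371 members, and 27 lists had at least 3 tested genes. They covered cold-response transcription factors, COR effectors, ABA and dehydration, ethanol and acetate metabolism, hypoxia, heat shock, the ER unfolded protein response, flavonoids, jasmonate, salicylate and immunity, aliphatic glucosinolates, photosynthesis, starch with raffinose and proline, carbon starvation, antioxidants, the morning and the evening clock, senescence, touch with wounding and early calcium, membrane lipids, growth, cell division, floral genes, markers of root, guard cells, epidermis and phloem, and reference genes. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Named genes were, per comparison, the 8 highest and 8 lowest log2 fold changes among called genes with at least 10 CPM in the higher group (for the difference of freezing effects, in any of its 4 groups), the 3 members of each list with the smallest p, or up to 6 where camera called the list, and ADH1, CBF1 to CBF3, COR15A, RD29A and the reference genes. Organelle genes were counted and not named.

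Alternatives were DESeq2 size factors (RLE) in edgeR, no filter on low counts beyond a total of 1, DESeq2 1.42.0, only the groups compared, the replicate number as a block, leaving out each library in turn, thinning all libraries to 2098593 counts, leaving out organelle genes, and a test against a fold change of 1.5 (glmTreat). Some alternatives were chosen after seeing the data: the transcript length trend of each library removed through offsets (natural spline with 4 degrees of freedom), with list tests at the preset and at an estimated correlation, and water replicate 6 and ethanol replicate 7 left out. The length slope of a library is that of log2 CPM, as the deviation from the gene's mean over 40 libraries, on log2 transcript length. Tests of list scores between groups were two-sided exact permutation tests, and the correlation of length slope with organelle share had a two-sided permutation test within groups with 100000 resamples. Each comparison was also repeated for 100 splits of its libraries, the real one included, and the difference of freezing effects again with each gene's mean ethanol effect, from an additive model, removed through offsets.

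The procedure was tested on simulated data with 200 changed genes among 16579. At fold changes of 1.5, 2 and 4 it recovered 44.8%, 80.6% and 93.9% of them for freezing after water, with 5 false calls, and 25.4%, 50.7% and 84.8% for the difference of freezing effects, with 10 false calls. False calls were 3.31% and 8.55% of all calls, the latter above the 5% set. Simulated counts were drawn independently, so no library stood apart by design. Length slopes of the observed size added to simulated data for freezing after water gave 983 false calls, and 6 with the trend removed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.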

Results

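Gene expression was measured in shoots of Arabidopsis thaliana, the thale cress, grown in pots of clay granule soil and sequenced with Lasy-Seq, a multiplexed RNA-seq protocol. The 40 libraries formed 5 groups of 8. The starting plants were 14 days old and had no pretreatment. Water plants and ethanol plants had then stood for 6 days with the bottoms of their pots in water or in 20 mM ethanol. Frozen water plants and frozen ethanol plants had gone through the same pretreatments and then an overnight freezing treatment at -4 °C, per the protocol in the labels, after which pots went back to the growth room for a stated time. The labels of both frozen groups carry a time of 2 h, and the sources used here do not say whether it counts freezing or the time after it. The hour of harvest of each group is not given in the sources used here, and the frozen plants had passed a night that the unfrozen plants set beside them may not have. The labels do not say whether replicates came from separate plants or pots, so p-values measure the spread between these samples. Library totals ran from 2098593 to 9211896 counts. Their mean ± SD (n = 8 per group) was 5480699 ± 1588219 counts in starting plants, 5125535 ± 1076993 in water plants, 5207151 ± 1716472 in ethanol plants, 4734365 ± 1292122 in frozen water plants and 6536832 ± 1343960 in frozen ethanol plants. A total of 3 counts corresponded to 1.43 CPM, counts scaled to the library total, in the shallowest library and 0.326 CPM in the deepest, a floor that covers counting error only. Of 27416 genes, 16579 were tested. Changes below are log2 fold changes ± SE between groups of 8 libraries, and a gene was said to rise or fall at an edgeR adjusted p under 0.05.

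**Figure D1:**
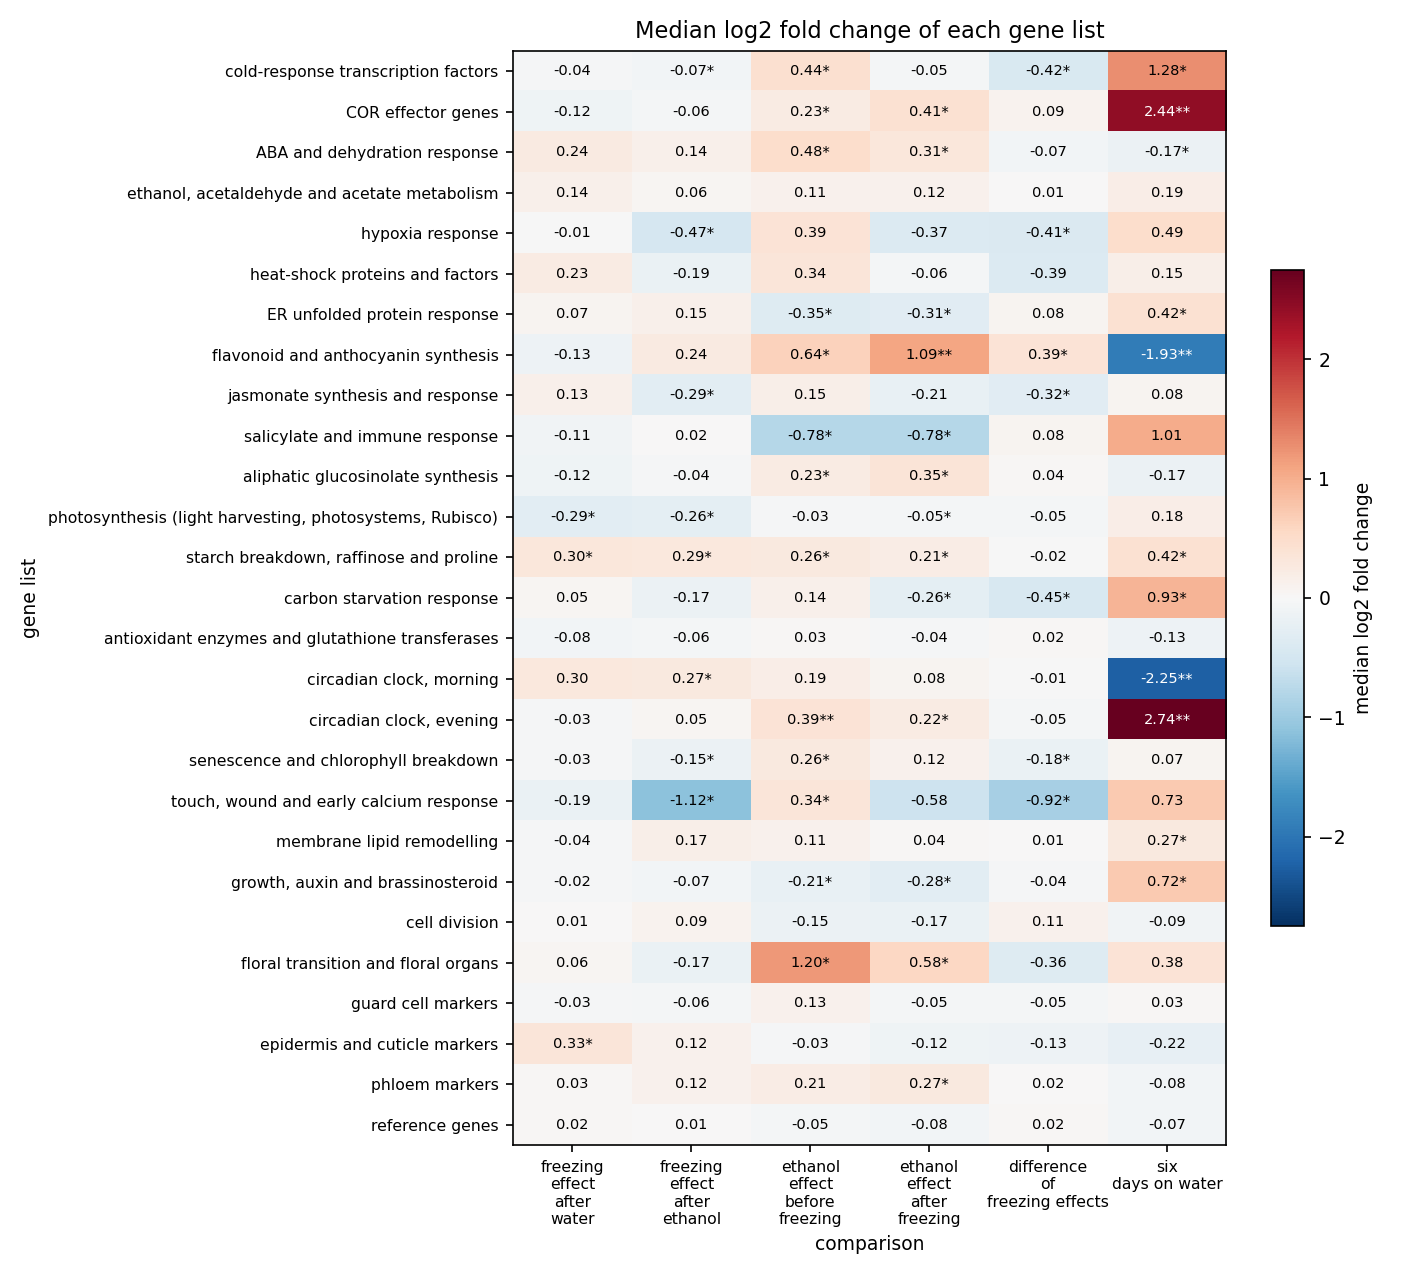
Median log2 fold change of each of the 27 gene lists tested (vertical axis) in each of the 6 comparisons (horizontal axis), with red for higher and blue for lower. One asterisk marks a camera adjusted p under 0.05 with the preset correlation, and a double asterisk marks lists that also passed with an estimated correlation, such as the evening clock list over 6 days on water, with a median of 2.74.

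The first comparison set water plants against starting plants, and so spans the 6 days of pretreatment. The labels give 1 age, 14 days, for all groups, as that of plants taken into pretreatment. Age, watering and the hour of harvest cannot be told apart for any change of this comparison. Clock genes moved in opposite directions. All 7 evening clock genes rose, among them ELF4 (AT2G40080; 3.74 ± 0.18) and PRR5 (AT5G24470; 3.26 ± 0.15), both repressors in the evening loop. Of 8 morning clock genes 7 fell, among them LHY (AT1G01060; -4.05 ± 0.23), from 32.4 ± 4.31 to 1.99 ± 1.06 CPM (SD), and CCA1 (AT2G46830; -3.04 ± 0.17), while PRR7 rose (0.62 ± 0.098). Among the COR effector genes, known for induction by cold, 16 of 17 rose, and 17 did when adjusted over the list alone. COR15A (AT2G42540; 2.98 ± 0.32) went from 49.95 ± 8.49 to 392 ± 175 CPM (SD), COR15B rose by 3.37 ± 0.24 and the RNA-binding protein gene GRP7 by 3.14 ± 0.077. In the flavonoid and anthocyanin synthesis list 12 of 15 genes fell, and 14 did when adjusted over the list alone, with CHS (AT5G13930), the entry enzyme of the pathway, at -2.23 ± 0.12 and F3H at -2.45 ± 0.16.

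In total 4067 genes changed over the 6 days, 1991 higher and 2076 lower, of which 617 rose and 466 fell at least 2-fold. Outside the lists, PORA, a chlorophyll synthesis enzyme, rose by 3.38 ± 0.26, and the early light-induced protein genes ELIP2 (-4.61 ± 0.17) and ELIP1 (-4.02 ± 0.17) and the ammonium transporter gene AMT1;2 (-3.38 ± 0.18) fell. The camera calls of the COR (adjusted p = 3.89e-25), flavonoid (2.69e-15), morning clock (1.05e-07) and evening clock (7.64e-18) lists held with an estimated correlation, at adjusted p = 0.00386, 0.00386, 7.47e-05 and 4.59e-09. Of the cold-response transcription factors 8 of 13 rose and 1 fell, or 9 and 2 when adjusted over the list alone, with CBF3 (AT4G25480) at 2.42 ± 0.31, MYB73 at 1.46 ± 0.15 and ICE1 at -0.44 ± 0.10. That list's adjusted p was 0.001, and 0.119 with an estimated correlation. CBF1 and CBF2 averaged 0.277 and 0.896 CPM in starting plants, near the floor of 3 counts.

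Sugar and growth genes changed too. Of the carbon starvation genes 8 of 10 rose, the same number when adjusted over the list alone, such as TPS11 (1.48 ± 0.17) and the asparagine synthetase gene ASN1 (1.51 ± 0.32; adjusted p = 0.119 for the list with an estimated correlation). In the list of starch breakdown, raffinose and proline genes 9 of 17 rose and 6 fell by both adjustments, with the starch enzyme genes PHS2 at 1.67 ± 0.085 and SEX1 at 1.51 ± 0.10 (adjusted p = 0.361 with an estimated correlation). Growth, auxin and brassinosteroid genes rose in 6 of 10 cases and fell in 3 by both adjustments, with IAA29 at 2.21 ± 0.20 and the expansin gene EXPA8 at 1.64 ± 0.11 (adjusted p = 0.121 with an estimated correlation). Of the endoplasmic reticulum (ER) unfolded protein response genes 8 of 12 rose, or 9 over the list alone, with PDIL1-1 at 1.06 ± 0.12 and UTR1 at 1.12 ± 0.21 (adjusted p = 0.361 with an estimated correlation), and water replicate 6 stood at a mean log2 CPM of 6.63 for this list. Abscisic acid (ABA) and dehydration genes fell in 6 of 17 cases by both adjustments, with HB12 at -1.29 ± 0.17 and HAB1 at -1.27 ± 0.20. The ABA list's adjusted p of 0.0446 became 0.431 with an estimated correlation, 0.0512 with the transcript length trend removed and 0.0763 without water replicate 6 and ethanol replicate 7, the pair of libraries with the lowest mean correlation with their groups.

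Some lists held changed genes with no call for the list over the 6 days. Salicylate and immune genes rose in 8 of 15 cases, or 9 over the list alone, with WRKY54 at 3.14 ± 0.41 and a list adjusted p of 0.0537. Water replicates 6 and 7 stood apart in this list. PR1 had 814 and 208.7 CPM in them, against 2.37 to 33.6 in the other 6 water libraries and 5.27 to 90.3 in starting libraries. PR2 had 511 and 70.8 CPM, against 2.91 to 9.74 in the other water libraries and 3.74 to 13.4 in starting libraries. Photosynthesis genes rose in 12 of 23 cases and fell in 6, or 13 and 9 over the list alone, with the Rubisco activase gene RCA at -0.70 ± 0.050 and the Rubisco gene RBCS2B at -0.74 ± 0.057, and a list adjusted p of 0.398. Of 7 ethanol, acetaldehyde and acetate metabolism genes, PDC2 (2.25 ± 0.13) and ADH1 (AT1G77120; 1.15 ± 0.20) rose and ACN1 fell (-1.11 ± 0.12), with a list adjusted p of 0.37 and the same calls over the list alone. Touch, wound and early calcium genes rose in 5 of 12 cases, or 6 with 1 fallen over the list alone (adjusted p = 0.319), jasmonate genes rose in 5 of 16 and fell in 1 by both adjustments (0.35), and hypoxia genes rose in 3 of 13, or 5 over the list alone (0.0565). Of the 10 listed root markers only PYK10 was tested, and it fell by 1.61 ± 0.25. Among 8 reference genes UBQ10 (-0.37 ± 0.052) and GAPC1 (-0.28 ± 0.059) fell, with a list adjusted p of 0.319.

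**Figure D2:**
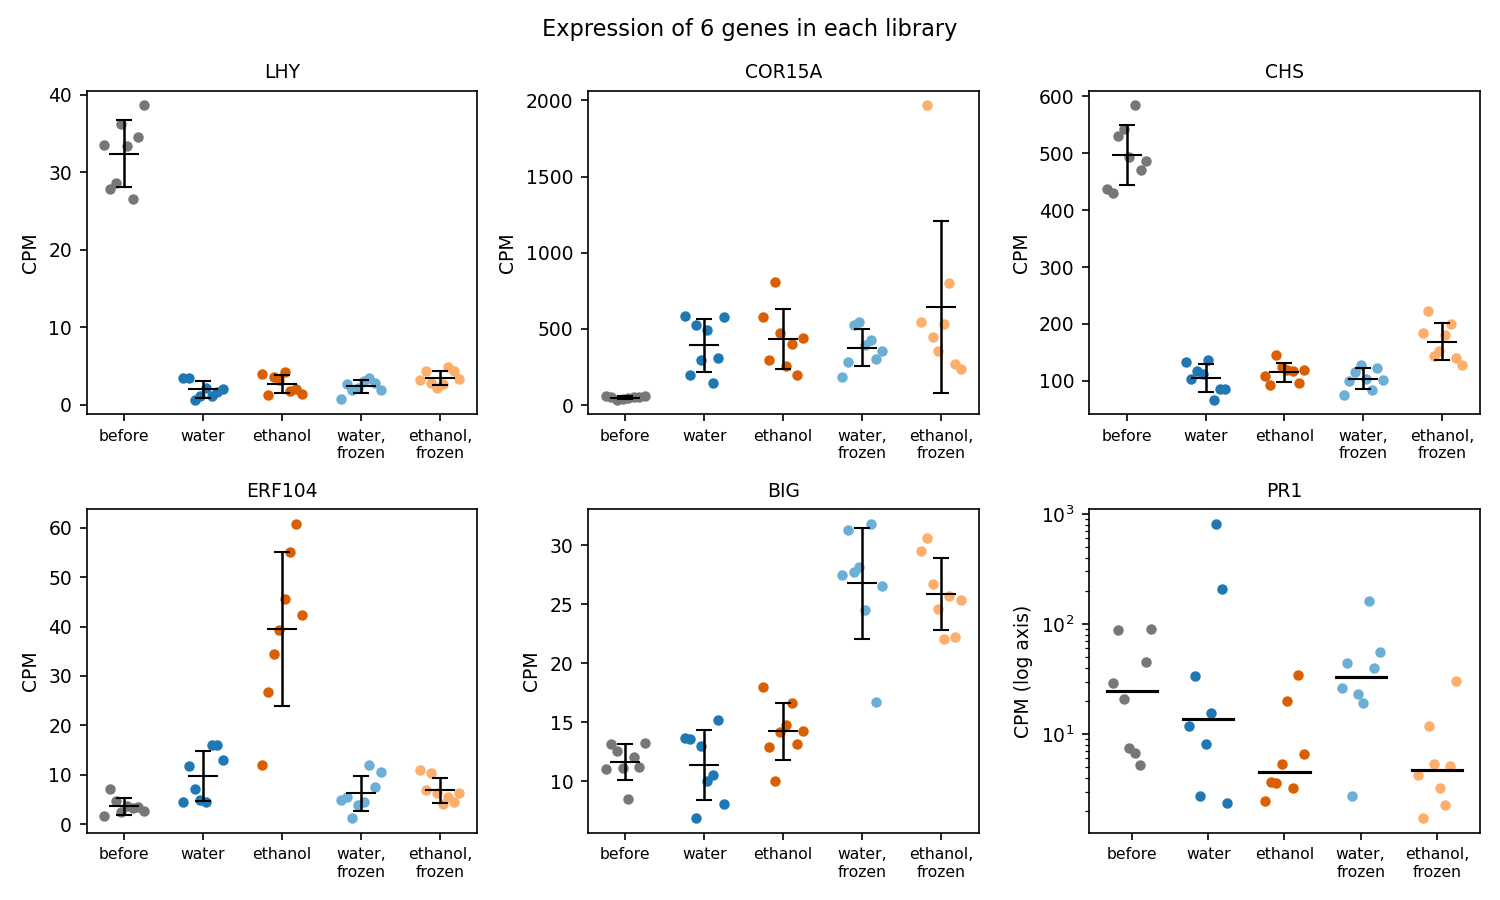
Expression in CPM (vertical axes) of LHY, COR15A, CHS, ERF104, BIG and PR1 in each of the 40 libraries, grouped along the horizontal axes as starting plants (before), water, ethanol, frozen water and frozen ethanol plants. Points are libraries, bars are the mean ± SD of 8, and the PR1 panel has a log axis with lines at the medians; ERF104 averaged 39.5 CPM in ethanol plants and between 3.61 and 9.72 CPM in the other groups.

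The comparison of ethanol plants with water plants before freezing addressed the effect of the ethanol pretreatment itself. Some early-response regulator genes were higher in ethanol plants. ERF104 (AT5G61600), an ethylene response factor gene, rose from 9.72 ± 5.08 to 39.5 ± 15.5 CPM (SD; 2.025 ± 0.28), and ERF6 (2.06 ± 0.47) and SZF1 (0.97 ± 0.26) rose with it. Of the touch, wound and early calcium genes 5 of 12 rose by both adjustments. Of the cold-response transcription factors 4 of 13 rose by both adjustments, among them ZAT6 (1.66 ± 0.37), MYB73 (0.83 ± 0.14) and RAV1 (0.70 ± 0.12), while CBF1 (0.44 ± 0.51), CBF2 (0.05 ± 0.49) and CBF3 (0.55 ± 0.25) did not pass the test (adjusted p = 0.687, 0.974 and 0.172). Both list calls (adjusted p = 0.000422 each) were lost with an estimated correlation, at adjusted p = 0.236 for the touch list and 0.148 for the cold-response list.

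Salicylate and immune genes were lower in ethanol plants, with 5 of 15 falling and 8 when adjusted over the list alone. PR1 (AT2G14610), a pathogenesis-related gene, averaged 9.93 ± 11.5 CPM in ethanol plants and 137 ± 282 in water plants (SD; -4.03 ± 0.84), NIMIN1 fell by 3.57 ± 0.67 (-2.42 without water replicate 6) and WRKY54 by 1.64 ± 0.37. Without water replicate 6, PR1 stood at -2.26 (adjusted p = 0.0269), and the calls of PR2 (-3.62 ± 0.72 with it, -1.28 without; adjusted p = 0.11), PR5 (-1.25 ± 0.41 with it, 0.08 without; 0.914), TAT3 (-3.80 ± 0.86 with it, -1.56 without; 0.192) and AT4G10500 (-4.47 ± 0.91 with it, -2.12 without; 0.0794) ended. The call of PR5 was also lost without water replicate 7 or ethanol replicate 1, 2, 3, 4 or 7. The call of the immune list (adjusted p = 0.0325) was lost with an estimated correlation, at adjusted p = 0.524, and without water replicate 6 and ethanol replicate 7, at 0.61. Genes of the ER unfolded protein response fell in 8 of 12 cases, or 10 over the list alone, with CNX1 at -0.57 ± 0.096 and UTR1 at -1.21 ± 0.22 (adjusted p = 5.14e-05, and 0.148 with an estimated correlation). The mean log2 CPM of that list was 6.63 in water replicate 6 and at most 5.75 in the other water libraries.

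In all, 1664 genes differed with ethanol before freezing, 670 higher and 994 lower, with 102 and 105 at 2-fold or more. AT4G01380 (2.62 ± 0.39) and AHP4 (AT3G16360; 2.15 ± 0.34), which encodes a histidine phosphotransfer protein, had the highest rises allowed by the rule for named genes, and AT4G15690, a glutaredoxin gene with near-identical neighbours, fell from 16.0 ± 3.73 to 1.93 ± 1.54 CPM (SD; -3.18 ± 0.27). Of the evening clock genes 3 of 7 rose, or 5 over the list alone, with ELF4 at 0.93 ± 0.14 and GI at 0.40 ± 0.11, and the list's call held with an estimated correlation (adjusted p = 0.00231 and 0.0475). Among COR effector genes COR28 (1.55 ± 0.19) and COR27 (1.47 ± 0.22), which encode regulators linked to the circadian clock and not protective proteins, rose and RCI2B fell (-0.79 ± 0.20), with 3 risen and 1 fallen of 17, or 5 and 1 over the list alone, while COR15A stood at 0.14 ± 0.29 (adjusted p = 0.839). That list's adjusted p of 0.00618 became 0.444 with an estimated correlation. The starch, raffinose and proline list had 7 of 17 genes higher by both adjustments, with SPS4F at 0.72 ± 0.13 and BAM3 at 0.53 ± 0.092 (adjusted p = 0.148 with an estimated correlation). Floral genes rose in 3 of 9 cases, or 5 over the list alone, with FUL at 1.25 ± 0.29 (0.0675 with an estimated correlation).

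Further lists were called before freezing with few members past the test. They were ABA and dehydration (3 of 17 rose, with HB7 at 0.77 ± 0.20), flavonoid synthesis (3 of 15 rose, 4 over the list alone), senescence (3 of 11 rose, with ORE1 at 1.39 ± 0.24), growth (3 of 10 fell, with SAUR19 at -1.41 ± 0.29 and EXPA1 at -0.48 ± 0.10) and aliphatic glucosinolate synthesis (2 of 16 rose, with MAM3 at 0.83 ± 0.22). With an estimated correlation their adjusted p was 0.148, 0.156, 0.148, 0.148 and 0.444. Among genes of ethanol and acetate metabolism, ACN1 (0.48 ± 0.12) and PDC2 (0.45 ± 0.12) rose and ADH1 stood at 0.25 ± 0.18 (adjusted p = 0.472), with 2 of 7 called by both adjustments and a list adjusted p of 0.0646. For cell division genes the list adjusted p was 0.198, with 2 of 11 lower over all genes and 1 higher and 2 lower over the list alone. Among guard cell markers SLAC1 rose (0.99 ± 0.22) as 1 of 6 by both adjustments (adjusted p = 0.252). The reference gene EF1A fell by 0.37 ± 0.061 as 1 of 8, or 2 over the list alone (list adjusted p = 0.252). After freezing 3 of these 8 were lower in ethanol plants, with 1 higher and 3 lower over the list alone (0.22).

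Freezing after water was the comparison of frozen water plants with water plants. Photosynthesis genes were lower after freezing, with 19 of 23 falling, or 20 over the list alone, such as the photosystem gene PSAD1 (AT4G02770; -0.41 ± 0.049), the light-harvesting gene LHCB3 (-0.39 ± 0.052) and the Rubisco gene RBCS1A (-0.35 ± 0.047). The share of counts from organelle genes was 2.03 ± 0.339% (SD) in water plants and 2.99 ± 0.626% in frozen water plants. Genes of starch breakdown, raffinose and proline were higher, with 8 of 17 rising, or 10 rising and 1 falling over the list alone, such as the starch-phosphorylating enzyme gene SEX1 (AT1G10760; 0.63 ± 0.093) and the amylase gene AMY3 (0.60 ± 0.084). Of the epidermis and cuticle markers 3 of 5 rose, or 4 over the list alone, with ATML1 at 0.61 ± 0.11 and CER6 at 0.33 ± 0.073. These 3 list calls (adjusted p = 9.91e-17, 6.53e-05 and 0.00284) were each lost with an estimated correlation, at adjusted p = 0.127 each. BIG (AT3G02260), needed for auxin transport, rose from 11.3 ± 2.97 to 26.8 ± 4.71 CPM (SD; 1.24 ± 0.13), and GLU1, a glutamate synthase gene, by 1.00 ± 0.068.

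After freezing on water the CBF genes, COR15A and RD29A did not pass the test, and no COR gene rose. CBF1 (-0.14 ± 0.52), CBF2 (0.11 ± 0.49), CBF3 (-0.07 ± 0.25), COR15A (-0.05 ± 0.29) and RD29A (0.39 ± 0.23) had adjusted p of 0.905, 0.92, 0.904, 0.934 and 0.28, and COR413IM2 fell (-0.32 ± 0.090) as 1 of 3 COR genes lower among 17 by both adjustments (list adjusted p = 0.4). With the transcript length trend removed none of the 17 COR genes was called in either direction. In total 2315 genes changed, 1161 higher and 1154 lower, with a median absolute log2 fold change of 0.428, and 48 rose and 18 fell at least 2-fold. TED7 (-1.22 ± 0.19) and AZI1 (-1.12 ± 0.21) fell, and AT5G10760 (-1.45 ± 0.45) stood at -0.07 without water replicate 6 (adjusted p = 0.92). The morning clock gene PRR7 (0.48 ± 0.094) and the evening gene GI (0.65 ± 0.11) rose, with list adjusted p of 0.062 and 0.711. With the transcript length trend removed neither rise was called: no gene of either list rose, and 1 evening gene fell.

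The changes after freezing followed transcript length. Across 16413 genes, which are not independent replicates, Spearman's correlation of the change with transcript length was 0.603 after water and 0.507 after ethanol. For the difference of both freezing effects it was -0.157. The median change after water went from -0.22 for 2149 genes with transcripts under 1000 bases to 0.578 for 122 genes over 6000 bases. In each of the 16 frozen libraries log2 CPM rose with length (slope 0.0807 to 0.237 per doubling, relative to the mean of all libraries), and in each of the 24 unfrozen ones it declined (-0.175 to -0.0207). The median transcript was 1295 bases long in the photosynthesis list, 2746 in the starch list and 2589 in the epidermis list, and that of BIG was 15700. With the length trend of each library removed, an alternative chosen after seeing the data, 362 genes were called after water, 291 of them among the 2315. BIG then stood at 0.62 ± 0.13 and GLU1 at 0.54 ± 0.067, 10 photosynthesis genes fell and 1 rose (adjusted p = 1.55e-09, and 0.952 with an estimated correlation), and the calls of SEX1 (0.18 ± 0.090; adjusted p = 0.357), of the starch list (0.382) and of the epidermis list (0.382) ended. No epidermis gene was then called, ATML1 and CER6 included, and 1 starch gene rose.

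**Figure D3:**
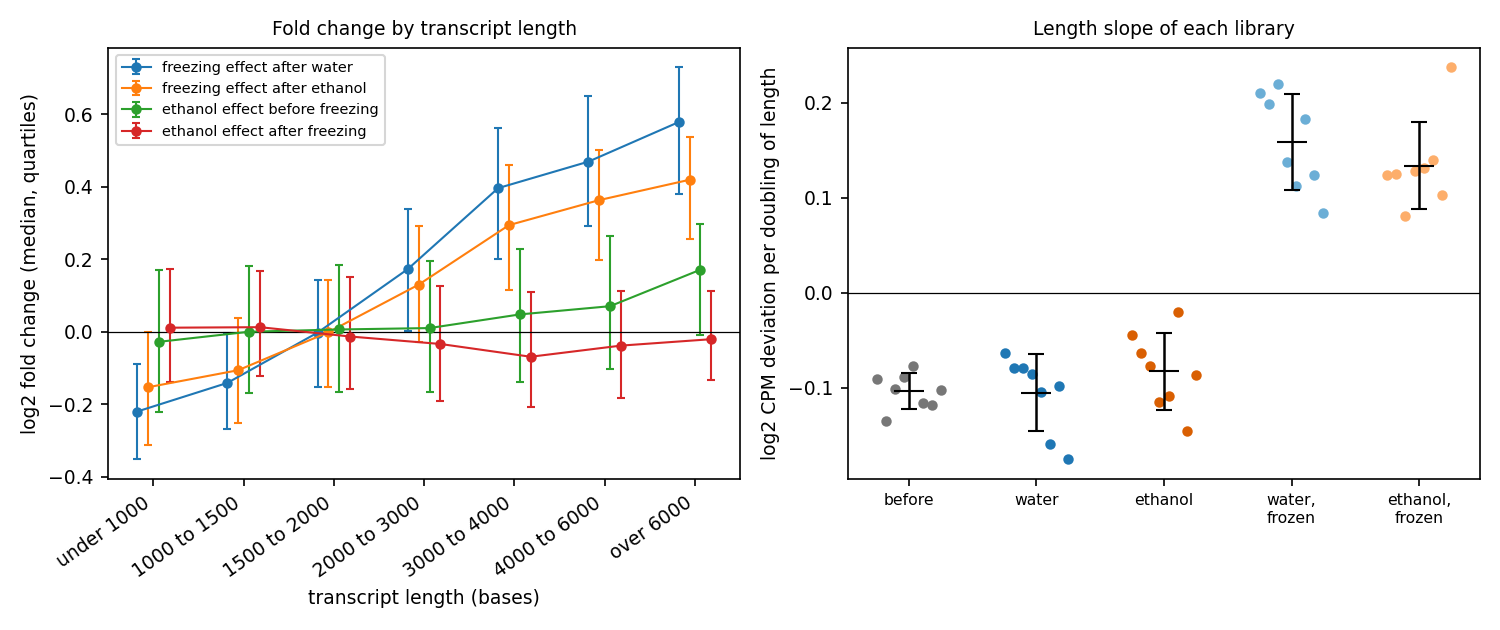
Left, median log2 fold change with quartiles (vertical axis) of genes in 7 bins of transcript length in bases (horizontal axis) for 4 comparisons; right, slope of log2 CPM on log2 transcript length in each library (points) with mean ± SD of 8 per group (bars). The 16 frozen libraries lie between 0.0807 and 0.237 and the 24 unfrozen ones between -0.175 and -0.0207.

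Freezing after ethanol was the comparison of frozen ethanol plants with ethanol plants, and early-response genes were lower in the frozen ones. Of the touch, wound and early calcium genes 9 of 12 fell by both adjustments. ERF104 went from 39.5 ± 15.5 to 6.86 ± 2.49 CPM (SD; -2.49 ± 0.28), ERF5 fell by 1.91 ± 0.32 and the xyloglucan enzyme gene TCH4 by 1.01 ± 0.23. Of the cold-response transcription factors 5 fell and 1 rose among 13 by both adjustments, with MYB73 at -1.09 ± 0.14 and RAV1 at -0.84 ± 0.11. The gene that rose was CBF2 (1.58 ± 0.45), which stood at 0.27 without frozen ethanol replicate 3 (adjusted p = 0.712). The adjusted p was 2.49e-08 for the touch list and 0.0107 for the cold-response list, and 0.115 and 0.304 with an estimated correlation.

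Photosynthesis genes fell in 19 of 23 cases after ethanol too, or 20 over the list alone, with LHCB2.1 at -0.48 ± 0.063 and PSAD1 at -0.39 ± 0.049 (adjusted p = 5.37e-20, and 0.115 with an estimated correlation). The organelle share was 2.43 ± 0.572% (SD) in ethanol plants and 3.41 ± 0.576% in frozen ethanol plants. The starch, raffinose and proline list had 7 genes higher and 1 lower of 17, or 8 and 1 over the list alone, with the sucrose phosphate synthase gene SPS1F at 0.52 ± 0.10 and the proline synthesis gene P5CS1 at 0.82 ± 0.18 (0.000228, and 0.15 with an estimated correlation). Hypoxia genes fell in 3 of 13 cases, or 4 with 1 risen over the list alone, among them HUP54 (-1.07 ± 0.21), and jasmonate genes in 3 of 16 by both adjustments, among them AOC2 (-0.47 ± 0.10). With an estimated correlation these lists had adjusted p of 0.115 and 0.595, and with the length trend also removed the hypoxia list had 0.0453. Of the morning clock genes LNK1 (0.52 ± 0.12) and 1 other of 8 rose by both adjustments (0.115 with an estimated correlation), and of the senescence genes NAP fell (-1.08 ± 0.25) as 1 of 11, or 3 over the list alone (0.385). The senescence call also ended without water replicate 6 and ethanol replicate 7 (adjusted p = 0.0501). Carbon starvation genes fell in 4 of 10 cases by both adjustments, among them BT2 (-2.03 ± 0.48; -1.41 without ethanol replicate 7) and SEN1 (-1.26 ± 0.32), with a list adjusted p of 0.0513. With the length trend removed 3 fell and the list was called (adjusted p = 0.000225, and 0.105 with an estimated correlation).

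In total 1621 genes changed with freezing after ethanol, 680 higher and 941 lower, with 18 and 124 at 2-fold or more. AT5G21940 (-2.42 ± 0.14), OXS3 (-2.28 ± 0.24) and BT5 (-2.12 ± 0.31) fell. With the length trend removed 783 genes were called, 517 of them among the 1621. The touch list then had 7 lower genes and the photosynthesis list 12 (adjusted p = 8.44e-12 each with the preset correlation, and 0.0453 and 0.21 with an estimated one), while the starch and morning clock calls ended (0.334 each). No morning clock gene was then called, LNK1 included, and 2 starch genes rose and 1 fell. With freezing 407 genes were higher and 481 lower in both pretreatments, where independent lists would share 47.6 and 65.5, and the changes correlated across genes at r = 0.434. These comparisons share no library, but the length trend is part of both.

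The test of whether freezing acted differently after ethanol than after water called 22 genes, 1 higher (BTF3, 0.42 ± 0.093) and 21 lower, where a lower value means a deeper fall or a smaller rise after ethanol. No gene was called higher with the length trend removed, with libraries thinned to equal depth or with only the groups compared. The count of 22 became 41 without the low-count filter, 46 with DESeq2, 42 without water replicate 6 and ethanol replicate 7, 9 with libraries thinned to equal depth and 1 in a test against a fold change of 1.5. At an unadjusted p under 0.05 there were 1347 genes. ERF104 differed by -1.91 ± 0.42, AT5G21940 by -1.54 ± 0.20 and the transcription factor gene RAV2 (AT1G68840) by -1.53 ± 0.25. These genes were higher in ethanol than in water plants before freezing, and RAV2 averaged 27.8 ± 11.9, 71.5 ± 16.3, 21.2 ± 4.61 and 18.9 ± 4.93 CPM (SD) in water, ethanol, frozen water and frozen ethanol plants. The touch list had 2 lower genes of 12, or 5 over the list alone (adjusted p = 2.65e-07), and the cold-response transcription factors 2 of 13, or 4 over the list alone (0.00023). Both had an adjusted p of 0.154 with an estimated correlation. Carbon starvation, jasmonate, senescence, hypoxia and flavonoid lists were called as well (adjusted p = 0.000839, 0.00101, 0.00526, 0.033 and 0.00858), with no member past the test over all genes and, over the list alone, 1 senescence gene lower and 1 flavonoid gene higher. With an estimated correlation their adjusted p was 0.154, 0.421, 0.231, 0.231 and 0.527. CBF3 (0.57 ± 0.35; adjusted p = 0.71), COR15A (0.63 ± 0.40; 0.739) and RD29A (0.22 ± 0.32; 0.929) did not differ by the test. Leaving out 1 library moved the count of 22 to between 11 (without ethanol replicate 8) and 61 (without water replicate 6), and by over 1.5 times without water replicate 1, 2, 3, 5 or 6, ethanol 4, 6, 7 or 8, frozen water 4, 5 or 6, or frozen ethanol 3, 4 or 5. The call of ERF104 ended without water replicate 1, 3, 4 or 5, ethanol 4, 6, 7 or 8, frozen water 6 or 8, or frozen ethanol 4, 5 or 7 (highest adjusted p = 0.0925), and that of BTF3 in 20 of 32 such fits (highest 0.0895).

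Ethanol plants and water plants were also compared after freezing. Flavonoid and anthocyanin synthesis genes were higher in frozen ethanol plants, with 11 of 15 rising and 13 when adjusted over the list alone. CHS averaged 169 ± 33.0 CPM against 104 ± 18.1 in frozen water plants (SD; 0.71 ± 0.11), and DFR (1.52 ± 0.29), TT19 (1.41 ± 0.27) and LDOX (1.11 ± 0.24) rose with it. The list's adjusted p was 4.32e-14, and 0.0187 with an estimated correlation. Of the COR effector genes 5 of 17 rose and 1 fell, or 13 and 1 over the list alone, with the clock-linked regulator genes COR28 at 1.37 ± 0.20 and COR27 at 1.21 ± 0.22 (adjusted p = 6.01e-05, and 0.262 with an estimated correlation). COR15A stood at 0.77 ± 0.29 (adjusted p = 0.112), with 1968 CPM in frozen ethanol replicate 2 and 234.9 to 799 CPM in the other 7 frozen ethanol libraries. Of the cold-response transcription factors CBF3 (1.12 ± 0.24) and CBF2 (1.51 ± 0.45) rose, 2 of 13 or 3 over the list alone, with a list adjusted p of 0.914, and CBF2 stood at 0.23 without frozen ethanol replicate 3 (adjusted p = 0.84) and lost its call without frozen water replicate 1, 2, 5 or 7.

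Salicylate and immune genes were lower after freezing too, with 5 of 15 falling, or 7 over the list alone, such as the regulator genes SARD1 (-1.78 ± 0.40) and WRKY70 (-1.07 ± 0.27). The fall of PR1 (-2.61 ± 0.81; adjusted p = 0.0431) ended in 12 of 16 fits that each left out 1 library, with the highest adjusted p of 0.176 without frozen water replicate 6 (-1.97). The immune list's adjusted p of 0.000101 became 0.262 with an estimated correlation. PAD3, an enzyme gene of camalexin synthesis, fell by 3.32 ± 0.68 and TAT3 by 4.03 ± 0.79. ER unfolded protein response genes fell in 3 of 12 cases, or 9 over the list alone, with CNX1 at -0.48 ± 0.095 (adjusted p = 2.09e-05, and 0.183 with an estimated correlation). Growth genes fell in 3 of 10, or 5 over the list alone, with EXPA1 at -0.51 ± 0.10 and IAA29 at -0.77 ± 0.17 (0.000429, and 0.0779 with an estimated correlation). Aliphatic glucosinolate genes rose in 3 of 16, or 9 over the list alone, with FMOGS-OX3 at 0.68 ± 0.17 (2.2e-05, and 0.25 with an estimated correlation). In the starch list 4 of 17 rose, or 7 with 1 fallen over the list alone, with BAM3 at 0.37 ± 0.091 (0.00148, and 0.183 with an estimated correlation).

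Other lists called after freezing were evening clock, with ELF4 at 0.81 ± 0.14 as 1 of 7 or 3 over the list alone, carbon starvation (1 of 10 lower, 3 over the list alone), phloem markers (2 of 5 higher by both adjustments, with SUC2 at 0.29 ± 0.069), floral genes (1 of 9 higher, 2 over the list alone), ABA genes (1 of 17 higher and 1 lower, 3 and 1 over the list alone, with RD26 at -0.87 ± 0.23) and photosynthesis genes (1 of 23 lower, 2 over the list alone). With an estimated correlation their adjusted p was 0.065, 0.183, 0.183, 0.183, 0.31 and 0.594, and with the length trend also removed the evening clock list had 0.0294. In total 870 genes differed, 400 higher and 470 lower, with 65 and 83 at 2-fold or more. AT4G01380 (2.83 ± 0.38), AHP4 (2.71 ± 0.35) and the sugar transporter gene SWEET13 (1.78 ± 0.32) rose. Of the genes higher after freezing 50.2% were also higher before it, where independent lists would share 4.04%, and 279 genes were lower both times, where 28.2 would be shared, with r = 0.521 across genes and no library in common. The 1 gene called in opposite directions was AT1G23390 (0.47 ± 0.12 before and -0.48 ± 0.12 after), named after its values were seen. Leaving out 1 library moved the count of 870 to between 556 (without frozen ethanol replicate 2; 576 without replicate 6) and 1089 (without frozen ethanol replicate 8).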

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

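Tests of organelle share, of immune genes, of time of day for early-response genes and the removal of length trends were chosen only after the results were seen. Predictions for the other tests below were written before those tests were run, some for patterns already seen in these data.

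Freezing was followed by changes that tracked transcript length, with Spearman correlations across genes of 0.603 after water and 0.507 after ethanol, and the length slope of frozen ethanol replicate 8 stood apart at 0.2365 (next 0.1405). The tables argue against depth or base composition as the whole cause: with libraries thinned to equal depth the correlation after water was 0.559, and the partial correlation given GC content was 0.581. RNA quality stays open, because the slope's relation within groups to the organelle share of counts had r = 0.341 (permutation p = 0.049 from 100000 resamples), rho = 0.282 (p = 0.0921) and, without frozen water replicate 7 and frozen ethanol replicate 8, r = 0.181 (p = 0.287). By the first form of this test, a permutation p under 0.05 for r, the relation passed, and the demand that it hold without those libraries was added after its value was seen. A response of the plants to freezing may also lie behind the trend, and it cannot be told apart from RNA quality here, because the slope was above 0 in 16 of 16 frozen and 0 of 24 unfrozen libraries.

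Immune genes were lower in ethanol plants before freezing, and a few libraries may carry much of the size. The median over the 5 called genes was -3.57 in the model and -1.22 as a difference of group medians (pseudocount 0.5 CPM), with PR1 at -4.03 and -1.5, PR2 at -3.62 and -0.286 and PR5 at -1.25 and 0.257. An effect of ethanol on the whole group stays open: the mean log2 CPM of the list was 2.82 ± 0.237 (SD) in ethanol and 3.37 ± 1.16 in water plants before freezing (n = 8 each; exact permutation adjusted p = 0.29), and 2.83 ± 0.4 and 3.64 ± 0.691 after it (exact adjusted p = 0.0236). Replicate 6 was highest for PR1, PR2 and PR5 in water plants (814, 511 and 444 CPM) and in frozen water plants (160, 112 and 105), though not in ethanol plants (PR1 at 3.27 before and 2.28 after freezing). Infection of single plants, or of plants kept together under 1 number, is a candidate source that the labels give no means to test.

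Of the early-response genes (touch, wound and early calcium), 5 of 12 rose in ethanol plants before freezing and 4 stood below 0, the lowest at -1.14 (adjusted p = 0.000422, and 0.236 with an estimated correlation), and the freezing effect after ethanol lay below that after water by a list median of -0.92 (2.65e-07, and 0.154 with an estimated correlation). The calls of single members rest near the threshold: 12 of 32 fits that left out 1 library called 0 members with edgeR, and the fit without water replicate 6 called 5. Another time of day at harvest stays open. The effects of ethanol on the evening and morning clock lists before freezing differed by 0.198 in their medians. That lay below the difference of 1 set for a shift and within the smaller bound set against one, both set after the values were seen. But with an estimated correlation camera called the evening list (adjusted p = 0.0475) and not the morning list (0.524), which a small shift could give. Handling is open, because the touch genes TCH2, TCH3 and TCH4 had a median of 0.151 before freezing against 0.449 for the other members, and an effect of ethanol itself may equally account for the pattern.

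Single libraries stood apart from the other 7 of their group in 13 of 170 groups of 8 values, by a gap above 0.526 of the group's range, and chance gives about 1 in 20 such groups. Starting replicate 1 had 18010 genes detected (nearest 18810), a mean correlation with its group of 0.9406 (nearest 0.9534), and mean log2 CPM of 4.977 for COR effectors (nearest 4.749) and 0.15 for heat shock genes (nearest 0.9763). Ethanol replicate 7 had a mean correlation of 0.9267 (nearest 0.9448). Starting replicate 1 and ethanol replicate 7 were also the shallowest libraries of their groups, with 2478955 and 2098593 counts, and the part of depth in these values was not tested. For the ER unfolded protein response, water replicate 6 stood at 6.631 (nearest 5.751), frozen water replicate 6 at 6.171 (nearest 5.869) and frozen ethanol replicate 8 at 5.685 (nearest 5.58). For flavonoid genes, starting replicate 6 stood at 4.854 (nearest 4.485) and water replicate 5 at 3.314 (nearest 2.706). Frozen ethanol replicate 3 had 4.566 for cold-response transcription factors (nearest 3.375), and frozen ethanol replicate 6 had 3.879 for morning clock genes (nearest 3.617).

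The effect of freezing differed between ethanol and water plants for 22 genes by edgeR's test of the difference, all listed here with log2 differences. Those with the lowest adjusted p were AT5G21940 (-1.541; adjusted p = 6.69e-06), AT1G80440 (-1.425; 0.000447), AT3G10020 (-0.8892; 0.000496), RAV2 (-1.526; 0.000496), AT3G15450 (-1.147; 0.000673), AT1G23390 (-0.9445; 0.00142), MYB77 (-1.362; 0.00417) and J8 (-0.8724; 0.00479). They were followed by GLU1 (-0.4655), MYB73 (-0.9603), AR781 (-1.446), AT5G19120 (-1.538), AT4G27280 (-1.534), ERF104 (-1.909), RAV1 (-0.7465), BTF3 (0.4177), ATCTH (-0.6398), RSH3 (-0.7193), AT4G05070 (-0.7031), AT3G59940 (-0.5097), SZF1 (-1.65) and AT2G24550 (-1.119), with adjusted p from 0.0153 to 0.0492. Genes among these that no rule for named genes had picked are given because they passed, and were chosen after their values were seen. With 1 library left out, BTF3 lost its call in 20 of 32 fits (highest adjusted p = 0.0895), SZF1 in 19 (0.123), RAV1 in 17 (0.0823), ERF104 in 13 (0.0925) and AT4G27280 in 9 (0.0654). MYB73 lost it without frozen water replicate 6 (-0.87; 0.0525) and AT5G19120 without ethanol replicate 7 (-1.39; 0.0503). AT5G21940, AT1G80440, RAV2 and AR781 kept theirs in each of the 32 fits. For the other genes these fits were not read gene by gene, but calls were lost among them too. Without ethanol replicate 8 only 11 of the 22 genes stayed called. With the transcript length trend removed 18 of the 22 stayed called, and BTF3 was not among them.

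For lists, the median difference of freezing effects was -0.425 for cold-response transcription factors, -0.406 for hypoxia, 0.385 for flavonoids, -0.319 for jasmonate, -0.449 for carbon starvation, -0.183 for senescence and -0.92 for touch, wound and early calcium genes. With an estimated correlation the adjusted p was 0.154, 0.231, 0.527, 0.421, 0.154, 0.231 and 0.154, so each call was lost.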

How the results depend on the processing

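The length-trend removal, with either correlation, and the fit without water replicate 6 and ethanol replicate 7 were chosen only after the results were seen. Counts of called genes are given in the order freezing after water, freezing after ethanol, ethanol before freezing, ethanol after freezing, difference of freezing effects and 6 days on water. Against 2315, 1621, 1664, 870, 22 and 4067, thinning to equal depth gave 921, 733, 821, 322, 9 and 2492, through fewer counts, and the test against a fold change of 1.5 gave 2, 48, 55, 34, 1 and 954, through its stricter hypothesis. With the length trend removed, freezing gave 362 and 783, and the difference gave 22, all lower, of which 18 were shared. The count of 22 became 41 without the low-count filter, 46 with DESeq2 and 42 without the pair of libraries named above; the cause was not tested. Leaving out 1 library each moved the 870 genes of ethanol after freezing to between 556 and 1089 and the 22 to between 11 and 61. Other counts under RLE, DESeq2, no filter, only the groups compared and no organelle genes lay within 1.5 times their value. PR5 in ethanol plants before freezing (-1.245) turned to 0.0824 with DESeq2 and 0.12 without the pair of libraries, and lay between -1.39 and 0.076 with 1 library left out, the latter without water replicate 6; the cause of the change with DESeq2 was not tested. Of the 55 list calls, 6 held with an estimated correlation, 40 with fry, 50 with the length trend removed and 52 without the pair. With the trend removed the lost calls were starch and epidermis after water (adjusted p = 0.382 each), starch and morning clock after ethanol (0.334 each) and ABA over 6 days (0.0512). Without the pair they were senescence on freezing after ethanol (0.0501), the immune list before freezing (0.61) and ABA over 6 days (0.0763). With the trend removed and an estimated correlation, 9 of the 55 held: hypoxia and touch on freezing after ethanol (0.0453 each), the evening clock in ethanol plants before (0.0425) and after freezing (0.0294), flavonoids after freezing (0.0199), and COR (0.0041), flavonoids (0.0041) and the morning (6.74e-05) and evening clock (3.32e-09) over 6 days. Calls were also gained. With the trend removed they were flavonoids (0.0964 to 0.00688) and carbon starvation (0.0513 to 0.000225) on freezing after ethanol, and ethanol metabolism in ethanol plants after freezing (0.0555 to 0.0271). Without the pair 9 were gained: immune (0.696 to 0.00545) and ER unfolded protein (0.708 to 0.013) on freezing after water, photosynthesis (0.0919 to 0.00063), jasmonate (0.0936 to 0.0158), heat shock (0.111 to 0.0247) and ethanol metabolism (0.0646 to 0.0412) in ethanol plants before freezing, ethanol metabolism after it (0.0555 to 0.0308), and immune (0.378 to 0.00149) and heat shock (0.197 to 0.0352) in the difference of freezing effects. Over all comparisons, thinning kept 276 calls of a named gene in a comparison, with a median absolute log2 fold change of 1.12 before thinning (quartiles 0.552 and 1.89), and ended 116, with a median of 0.708 (0.407 and 0.96).

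Replicate numbers are shared between groups and paired the samples weakly if at all. Correlations of same-numbered libraries' deviations ran from -0.12 to 0.33. The highest was replicate 6 of water and frozen water plants, with 0.088 or less for the other numbers of these groups. By pair of groups, 0 to 4 of 8 libraries correlated best with their own number, with 4 for water and ethanol plants. A weak pairing is not excluded. With the replicate block the count for the difference of freezing effects was 36 and the other counts were 2327, 1702, 1666, 917 and 4045. With the block, 11 calls of a named gene in a comparison were lost and 389 held, no list call was lost, and over 6 days the hypoxia (0.0565 to 0.0413) and immune (0.0537 to 0.035) lists were gained.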

Other observations

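The nitrate test was chosen after glutaredoxin genes were seen to be low in ethanol plants, with its prediction written before it was run, and the clock test over 6 days and the splits with the ethanol effect removed were chosen only after the results were seen.

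Antioxidant genes changed in mixed directions over 6 days on water, with 2 of 14 higher and 6 lower, or 3 and 6 adjusted over the list alone. The catalase gene CAT3 rose by 1.52 ± 0.079, while CAT2 fell by 1.80 ± 0.073 and the ascorbate synthesis gene VTC2 by 1.27 ± 0.077 (list adjusted p = 0.147). In ethanol plants DHAR1, which recycles ascorbate, was higher before (0.49 ± 0.12) and after freezing (0.61 ± 0.12). Membrane lipid remodelling genes rose in 7 of 13 cases over the 6 days and fell in 3 by both adjustments, with the desaturase gene ADS2 at 1.64 ± 0.067 (adjusted p = 0.00653, and 0.119 with an estimated correlation). After freezing on water TIL fell by 0.59 ± 0.081 and the phospholipase gene PLDA1 rose by 0.44 ± 0.071, with 2 of 13 higher and 2 lower (0.861). With the transcript length trend removed, no gene of this list was called higher after freezing on water, PLDA1 included, and 1 was lower. Heat shock genes rose in 2 of 11 cases over the 6 days, with MBF1C at 0.81 ± 0.17 (0.376).

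Nitrate-induced genes were lower in ethanol plants, as a hypothesis drawn from these data. Of 10 tested, 5 fell before freezing (median -0.447; camera p = 0.00516 at the estimated correlation) and 7 after it (median -0.777; p = 3.26e-05). The nitrate reductase gene NIA2 stood at -0.85 ± 0.15 before and -1.18 ± 0.15 after, and the nitrite reductase gene NIR1 at -0.82 ± 0.13 and -0.80 ± 0.13. NIA1 stood at -0.32 ± 0.14 before freezing (adjusted p = 0.153). Lower nitrate signalling may be behind this, and single libraries were not left out for this list.

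Over 6 days on water the medians of the evening and morning clock lists differed by 4.99, which may reflect another time of day at harvest. The labels give no hour of harvest, so no change of that comparison, in clock and COR genes or in any other, can be assigned to age, watering or hour.

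For each comparison 100 splits of its libraries into groups of the same sizes were counted, the real one included. In each, 1 of the 100, the real one, called as many genes, the lowest share that 100 splits can give. The splits treat libraries as independent, which the labels do not settle, so chance is made unlikely and not excluded. Splits for the difference exchanged ethanol and water libraries within frozen and within unfrozen plants, which mixes the ethanol effect into the spread. With each gene's mean ethanol effect removed first, 1 of 100 splits, the real one, called 22 genes and the highest other called 9. The real counts and the highest others were 2315 and 417 for freezing after water, 1621 and 56 for freezing after ethanol, 1664 and 287 for ethanol before freezing, 870 and 137 after freezing, 22 and 14 for the difference, and 4067 and 2415 for 6 days on water.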
